A study of Rattus norvegicus with 9 samples.

How the data were processed

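RNA sequencing of rat heart was compared in 9 libraries, 3 in each of 3 groups of Sprague-Dawley rats. TAC libraries come from adult left ventricle after transverse aortic constriction, an operation that loads the heart with pressure. Sham libraries come from adult left ventricle after the same surgery without constriction. Fetal libraries come from the ventricle at embryonic day 18, and their titles number them as litters 1 to 3. Replicate number and the TAC and sham groups were read from the sample titles, and the fetal group from the developmental stage in the labels. The time between surgery and sampling is not given in the sources used here, and the adult labels do not say whether each library is a separate animal. Fetal RNA was isolated with Trizol and adult RNA with a column kit, so age, region of the heart and isolation cannot be separated.

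Libraries were made with the Illumina TruSeq RNA kit, which does not mark the strand, and were sequenced on the Illumina GAIIx. According to the submitters' processing notes, reads were aligned to the rat genome build rn4 with TopHat 1.3.1 and assembled with Cufflinks 1.0.3, with Cuffdiff, whose version is not given in the sources used here. The deposited FPKM values (fragments per kilobase of transcript per 1e6 mapped fragments, as the authors name them) come with confidence bounds per gene and per isoform. In each library they are multiplied by a further constant: the medians of the values above 0 run from 2.7e6 to 4.6e7. The deposited FPKM values therefore compare genes within a library, and were rescaled before libraries were compared. A plan to use them without rescaling was dropped for this reason, and median-of-ratios scaling, until then an alternative, took its place.

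Fragment numbers implied by the confidence bounds, in units of 1e6, were 7.03, 6.37 and 11.65 in TAC replicates 1 to 3, 18.07, 17.55 and 25.75 in fetal, and 14.04, 11.89 and 21.58 in sham. They are estimates: between 69.1% and 81.7% of low values with a single isoform gave whole fragments. At the median tested locus a library held between 57 and 242 implied fragments. Reference loci held between 87.95% and 94.21% of the fragments. The 10 largest genes held between 18.01% and 38.34%.

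The deposited gene names differ between libraries, because each library was assembled separately. Values were joined through the reference transcripts that the assemblies keep by name. There are 39492 of these, and 2 of them were placed in the same locus where they shared a gene in at least 5 libraries. This gave 29346 loci, 6351 of them with 2 or more reference transcripts. The value of a locus is the sum over its reference transcripts and the transcripts assembled with them. Loci of at least 200 nt were kept. Symbols come from the deposited files: 15968 of 24672 loci of that length have a symbol, and many loci with several transcripts have none. Several well-known heart genes, such as Myh6, Myh7, Ttn and Atp2a2, could therefore not be looked up by name and are not analysed here.

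Scale factors were the median of ratios over the 13137 loci above 0 in every library, followed by a common factor giving a mean library total of 1e6. Values in the text are rescaled FPKM, as mean ± SD with n = 3 per group, and loci at 0 throughout a group are given as listed at 0. Loci and transcripts with a value of at least 1 in at least 3 libraries were tested on the log2(value + 1) scale, which understates the fold change of weakly expressed genes. The share of a transcript in its locus was tested as log2((transcript + 1)/(rest of the locus + 1)), for loci with a mean of at least 3 and shares with a mean between 5% and 95%. All 9 libraries were fitted together with limma 3.58.1 (lmFit, eBayes with a trend, 6 residual degrees of freedom per feature), with a Benjamini-Hochberg adjusted p below 0.05 as the threshold. The p-values measure the spread between libraries of a group, which may be technical in the adult groups. A group listed at 0 throughout shows no spread and so lowers the spread estimated for that feature.

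Gene lists (21, fixed by name) were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Fry asks whether a list moves as a set, and its mixed form whether members move in any direction. Lists with fewer than 5 measured members, which were the adult sarcomere and calcium handling genes and the adipocyte markers, were not tested. Genes without a symbol in the files or below the filter were not measured. Measured were 17 of 31 genes of fatty acid oxidation, 12 of 24 fetal and stress genes and 21 of 52 matrix genes. Of splicing regulators 17 of 58 were measured, and of genes with known developmental splicing 11 of 62. The result of a list speaks for its measured members. For the overlap between comparisons, 100 data sets were simulated with the same shared sham libraries, no difference in any group and no pairing. Software for counts was not used, since the files hold no counts. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, networkx 3.6.1 and matplotlib 3.10.9.

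Genes to be named were chosen by rule. It takes the 10 largest changes per direction among called loci with a symbol, a mean of at least 5 in the higher group and no overlap between the libraries of the groups. Where fewer than 5 pass, the smallest p-values fill the direction up to 5. It adds up to 4 genes per list with the smallest adjusted p, and Nppa, Nppb, Acta1, Rbm20 and Pkm (Pkm2 in the files) among others where measured. Transcripts and shares followed the same rule, and a part of the genes it gives is named in the text. Genes named outside it were chosen after their values were seen, and the text says so. The groups, comparisons, tests, lists, naming rule and the first set of alternatives were chosen before the data were examined.

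The fit was tested on simulated data made from the means of the sham libraries and the spread within groups of all 9 libraries. Features were drawn independently, and 200 were changed in TAC in each of 10 draws. Of the changed genes, 3.4% were recovered after a 1.5-fold change, 19.4% after 2-fold, 56.4% after 4-fold and 74.6% after 8-fold, with 3.3 false calls per draw. Among genes with a mean above 10 the recovery at 2-fold was 29.7% and at 4-fold 78%. Of transcripts, 0.4% were recovered at 2-fold, 10.2% at 4-fold and 25.6% at 8-fold. Share calls recovered almost nothing at small changes (2.7% at 8-fold), so larger ones were added: 30% at 32-fold, 52.7% at 128-fold and 70% at 512-fold. A list lowered by 1.5-fold, that of fatty acid oxidation, was called in 10 of 10 draws by camera at the preset correlation. Its members were simulated independently, whereas their estimated correlation in the data was 0.274, so the draws do not measure recovery in the data.

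Alternatives changed one choice at a time: the pseudocount, the filter, the scaling, the prior variance, the libraries fitted, the share measure, a block for replicate number, and leaving out each library. Alternatives added after the data were seen were the values as deposited, equal library totals, reference transcripts only, no minimum length, a covariate for the library batch, replicates 2 and 3 only, and libraries weighted by their spread.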

Results

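The libraries ask which transcripts of the fetal heart return when the adult heart is overloaded, and whether the choice between transcripts of a gene returns with them. Fetal ventricle was therefore compared with sham-operated adult left ventricle, TAC with sham, and fetal with TAC. The fetal libraries stood apart: the first principal component separated fetal from adult libraries and held 56.5% of the variance. The second (16.9%) separated replicate 1 of each group from replicates 2 and 3. The shortest assembled feature was 43 nt in replicate 1 of each group and 63 nt in the other libraries, so replicate 1 is treated as a separate library batch. After removal of the group means, libraries with the same number correlated with each other in every pair of groups (0.47, 0.52 and 0.45 for number 1, 0.23, 0.26 and 0.21 for number 2, 0.17, 0.14 and 0.16 for number 3). Different numbers among replicates 2 and 3 correlated as well (0.29 for TAC 3 and sham 2, 0.22 for TAC 3 and fetal 2, 0.18 for fetal 2 and sham 3), so what sets the numbers apart is mainly replicate 1. As every same-number value lies above 0.1, values with a replicate block are given where it was run and changes a call or moves a count by more than 1.5-fold.

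Fetal ventricle differed from sham left ventricle at 6415 of 14143 loci, 3155 higher and 3260 lower in fetal. Every measured cell cycle gene (28 of 28) rose and every measured gene of fatty acid oxidation (17 of 17) fell. Tnni1, the slow skeletal troponin I of the fetal heart, rose from 8.04 ± 9.45 to 2503 ± 400.3 (log2 change 8.61, adjusted p = 0.000213; rn4 chromosome 13, from 48830442 to 48841258). Rpl3l, the muscle form of ribosomal protein L3, fell from 458.2 ± 96.2 to 0.140 ± 0.0241 (log2 change -8.63, adjusted p = 1.19e-07). Among regulators of splicing, 14 of 17 rose and 1 fell.

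Igf2, a growth factor of the fetus, rose from 24.3 ± 11.2 to 1018 ± 370.1 (log2 change 5.40, adjusted p = 2.53e-05), and Bmp7, a bone morphogenetic protein, from 0.547 ± 0.275 to 65.7 ± 4.49 (5.44, adjusted p = 2.43e-06). Bex1, a gene of the brain-expressed X-linked family, rose from 10.3 ± 2.52 to 542.2 ± 97.5 (5.60, adjusted p = 2.72e-06). Ccna2 (cyclin A2) rose from 1.86 ± 1.12 to 99.8 ± 25.2 (5.19, adjusted p = 6.08e-05) and Slc16a3, a lactate exporter, from 1.66 ± 0.636 to 107.2 ± 10.7 (5.37, adjusted p = 0.00032). The embryonic globin Hbe1 stood at 279.5, 89.9 and 51.7 in fetal replicates 1 to 3, and at 3.79, 0 and 0 in sham (6.03, adjusted p = 0.00142). Globin, Bex and myosin light chain genes have close paralogs, and reads may be shared between them.

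Myom2, a protein of the M band, fell from 1291 ± 268.7 to 3.43 ± 1.77 (log2 change -8.24, adjusted p = 9.92e-07). Aqp7, a glycerol channel, fell from 287.2 ± 77.7 to 0.872 ± 0.119 (-7.23, adjusted p = 6e-07) and Acss1, a mitochondrial acetate enzyme, from 359.3 ± 107.5 to 1.90 ± 0.695 (-6.95, adjusted p = 1.08e-06). Akr1cl1 (-8.19), Gda (guanine deaminase, -5.98), the class II histocompatibility gene RT1-Da (-6.05) and the interferon-induced Gbp1 (-5.74) fell too. With reference transcripts only, Rpl3l (adjusted p = 0.281, lowest over all alternatives 5.03e-08) and the fetal-high Tnni1 (0.23, lowest 4e-05) were no longer called and Myom2 turned to a log2 change of 2.03. All other alternatives kept the calls of Rpl3l and Tnni1.

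Of the 4 metabolic lists 3 were lower in fetal. In fatty acid oxidation, Lpl (lipoprotein lipase) fell from 1278 ± 195.9 to 57.1 ± 2.93 (log2 change -4.45, adjusted p = 1.23e-06), Acadm from 1254 ± 188.8 to 117.3 ± 12.9 (-3.40, adjusted p = 3.99e-06), Mlycd from 217.2 ± 13.8 to 31.4 ± 5.21 (-2.76) and Acads from 384.2 ± 44.4 to 60.7 ± 4.47 (-2.64). The list's median was -2.64 (camera adjusted p = 1.29e-12; adjusted p = 0.086 with an estimated correlation). In the tricarboxylic acid cycle 8 of 9 fell, among them Sucla2 from 678.2 ± 119.2 to 213.5 ± 13.9 (-1.65), with a median of -1.05 (adjusted p = 0.00035; adjusted p = 0.15 with an estimated correlation). In oxidative phosphorylation 19 of 28 fell, among them Uqcrc1 (-1.86) and Ndufs3 (-1.85), with a median of -1.22 (adjusted p = 2.13e-05; adjusted p = 0.319 with an estimated correlation). Glycolysis moved in both directions, with 5 of 15 higher and 3 lower and a median of 0.01 (adjusted p = 0.541). The glucose transporter Slc2a1 rose from 16.7 ± 2.36 to 151.6 ± 13.8 (3.11, adjusted p = 3.54e-06), while the muscle enzymes Pfkm (-1.94) and Pgam2 (-4.49) and the lactate dehydrogenase subunit Ldhb (-2.50) fell.

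Proliferation and splicing genes rose. Mcm6, a replication helicase subunit, rose from 4.50 ± 0.482 to 86.0 ± 3.40 (log2 change 3.99, adjusted p = 3.49e-06), and Mcm3 (3.41) and the centromere gene Cenpf (4.62) rose too. Ccne2 (cyclin E2) was listed at 0 in all 6 adult libraries and stood at 28.8, 19.4 and 30.1 in fetal. The cell cycle list had a median of 3.93 (camera adjusted p = 2.25e-17; adjusted p = 0.086 with an estimated correlation). Ptbp2, the neuronal polypyrimidine tract protein that represses exons, rose from 8.94 ± 0.708 to 48.2 ± 2.31 (2.31, adjusted p = 3.45e-05). Hnrnpu (1.46), Snrpa1 (1.19) and Sfrs10 (1.57) rose, and Khdrbs3 fell (-0.98, adjusted p = 0.00687). The splicing regulators had a median of 1.17 (adjusted p = 5.23e-05; adjusted p = 0.0609 with an estimated correlation). Rbm20, which controls titin splicing, rose from 37.4 ± 9.47 to 57.9 ± 8.91 (0.63, adjusted p = 0.0438). The call of Rbm20 was lost with a replicate block (adjusted p = 0.0523) and without TAC replicate 1 (0.0531) or 2 (0.0573), fetal replicate 2 (0.131) or 3 (0.108), or sham replicate 1 (0.135) or 2 (0.108). It was lost as well without a filter (0.0579), without a trend (0.0554), with only the libraries compared (0.0572), with replicates 2 and 3 alone (0.104) and with reference transcripts only (0.467), within a range from 0.000242 to 0.467.

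The list of fetal and stress genes had 5 of 12 higher and 1 lower, with a median of 1.35 (camera adjusted p = 0.034; adjusted p = 0.353 with an estimated correlation). Its call was lost with the filter of 5 (0.0665), without sham replicate 3 (0.0515) and on the values as deposited (0.192). Myl9 rose from 90.8 ± 30.7 to 1619 ± 214.9 (log2 change 4.18) and Ankrd1, a stress-responsive titin partner, fell from 2231 ± 129.2 to 810.1 ± 108.8 (-1.47, adjusted p = 0.00284). Nppa (atrial natriuretic peptide) missed the threshold (2.03, adjusted p = 0.05) and was called with a replicate block (0.0143), with the batch covariate (0.00958), with replicates 2 and 3 alone (0.033), and without TAC replicate 1 (0.0174), TAC replicate 2 (0.0324) or sham replicate 1 (0.0498), within a range from 0.0027 to 0.156. Nppb (0.45, adjusted p = 0.443), Acta1 (1.56, adjusted p = 0.0563, but 0.0424 without sham replicate 1) and Pkm2 (adjusted p = 0.445) were not called. Matrix genes went both ways, with 5 of 21 higher and 6 lower, a median of -0.06, a mean of 0.05 and a downward test (adjusted p = 0.723). Postn rose from 13.2 ± 9.37 to 269.6 ± 82.1 (adjusted p = 0.00015), Mfap5 fell by 4.98 on the log2 scale, and Dcn fell from 681.9 ± 152.9 to 83.3 ± 9.14. Immediate early genes had 3 of 25 higher, among them Myc (2.33), and 9 lower, among them Dusp1 (-1.85) and Hspa1a (-2.32), with a median of -0.34 (adjusted p = 0.232). Genes with known developmental splicing, of which 11 of 62 were measured, had 4 of 11 higher, among them Pdlim3 (1.34) and Vcl (0.80), with a median of 0.34 (camera adjusted p = 0.144).

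Markers of several cell types moved as well, so part of the changes in whole ventricle can come from its make-up of cells. Macrophage markers fell (11 of 15, median -1.72, camera adjusted p = 0.0003; adjusted p = 0.086 with an estimated correlation), C1qa from 60.7 ± 9.63 to 8.65 ± 1.81 (log2 change -2.69), with Lyz2 (-3.01) and Csf1r (-2.09). Lymphocyte markers fell (6 of 9, median -1.66, adjusted p = 0.00447; adjusted p = 0.086 with an estimated correlation), among them Ccl5 (-4.44) and Cd4 (-3.40). Fibroblast markers fell (8 of 13 lower, 1 higher, median -1.16, adjusted p = 0.0259; adjusted p = 0.412 with an estimated correlation), among them Dpt (-3.57) and Clec3b (-2.39). Erythroid markers rose (4 of 9, 1 lower, median 1.15, adjusted p = 0.0479; adjusted p = 0.345 with an estimated correlation) and so did epicardial markers (3 of 7, median 0.97, adjusted p = 0.034; adjusted p = 0.345 with an estimated correlation), among them Tbx18 (2.37) and Aldh1a2 (2.07). The erythroid call was lost with a pseudocount of 0.1 (0.0722), the filter of 5 (0.266), only the libraries compared (0.087), weighted libraries (0.0517), replicates 2 and 3 alone (0.381) and without any 1 library other than TAC replicate 1 or sham replicate 3 (0.0516 to 0.123). The epicardial call was lost with weighted libraries (0.0517), replicates 2 and 3 alone (0.0971) and without fetal replicate 1 (0.0572) or sham replicate 1 (0.0527) or 2 (0.0603), and the fibroblast call with reference transcripts only (0.117). With the filter of 5 the epicardial and lymphocyte lists had too few members to be tested. Not called as lists were endothelial (1 of 11 higher and 6 lower, median -0.45, adjusted p = 0.206), smooth muscle (3 of 7 higher and 1 lower, 0.43, adjusted p = 0.144), atrial and conduction (3 of 10 higher, 0.51, adjusted p = 0.148) and neural markers (1 of 8 higher and 3 lower, -0.74, adjusted p = 0.232). Gja5, the conduction connexin 40, rose from 7.57 ± 0.886 to 89.3 ± 17.6 (3.38, adjusted p = 6.01e-06). The atrial light chain Myl7 rose (4.24, adjusted p = 0.0369), with the call lost without TAC replicate 2 (0.0502), fetal replicate 1 (0.0859), 2 (0.0945) or 3 (0.0665), or sham replicate 3 (0.0597), within a range from 0.00352 to 0.618.

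**Figure D1:**
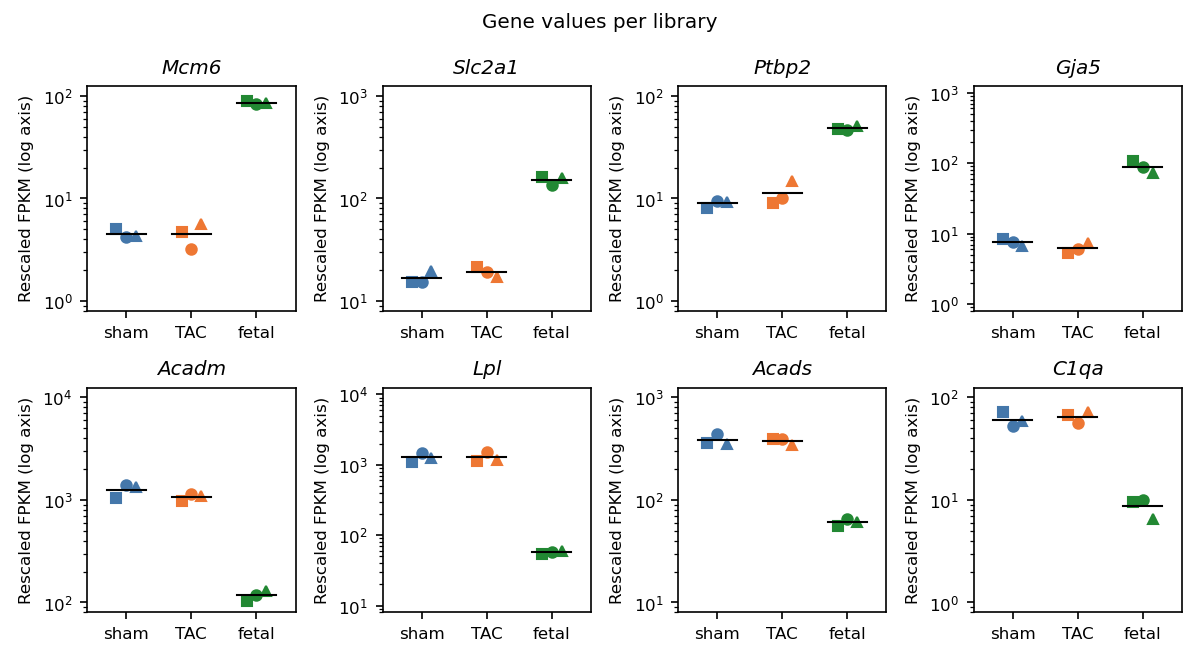
Rescaled FPKM of 8 genes in each library, on a log axis, with replicates 1, 2 and 3 as squares, circles and triangles and the group mean as a line. Between fetal and sham, Mcm6, Slc2a1, Ptbp2 and Gja5 rose and Acadm, Lpl, Acads and C1qa fell; none of the 8 was called between TAC and sham.

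The test was limma on all 9 libraries (n = 3 per group), and 45.4% of the loci passed. Of the called loci 2037 were more than 2-fold higher and 2190 more than 2-fold lower. The median of all loci shifted by 0.04. It shifted by 0.18 with equal library totals, where 5653 loci were called, and by 2.81 on the values as deposited, where 11164 were higher and 374 lower, so changes there were read relative to the shift. Camera called 11 of 19 lists at the preset correlation and 0 with an estimated one, fry called 16 and its mixed form 19. Adjusted over the list alone, the counts differed for the fetal programme (7 higher), the matrix (7 higher), lymphocytes (7 lower), erythroid markers (5 higher) and atrial markers (2 higher). On the values as deposited, the tricarboxylic acid cycle list lost its call and its direction (adjusted p = 0.862), and oxidative phosphorylation (0.537), fetal and stress genes (0.192), fibroblast (0.197), erythroid (0.649) and epicardial markers (0.537) lost their calls. Replicates 2 and 3 alone gave 5030 loci and 10 lists. With reference transcripts only, 2056 loci passed and Dcn (1.59), Col12a1 (-0.30), Mcm3 (-1.20), Tgfb2 (-0.48), Vwf (1.75) and Esam (0.0424) also turned. Ptbp2 (adjusted p = 0.124), Cenpf (0.981), Slc16a3 (0.412), Vcl (0.462), Clec3b (0.496), Cd4 (0.91) and Tbx18 (0.061) lost the call there, and so did Rbm20 and Myl7.

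**Figure D2:**
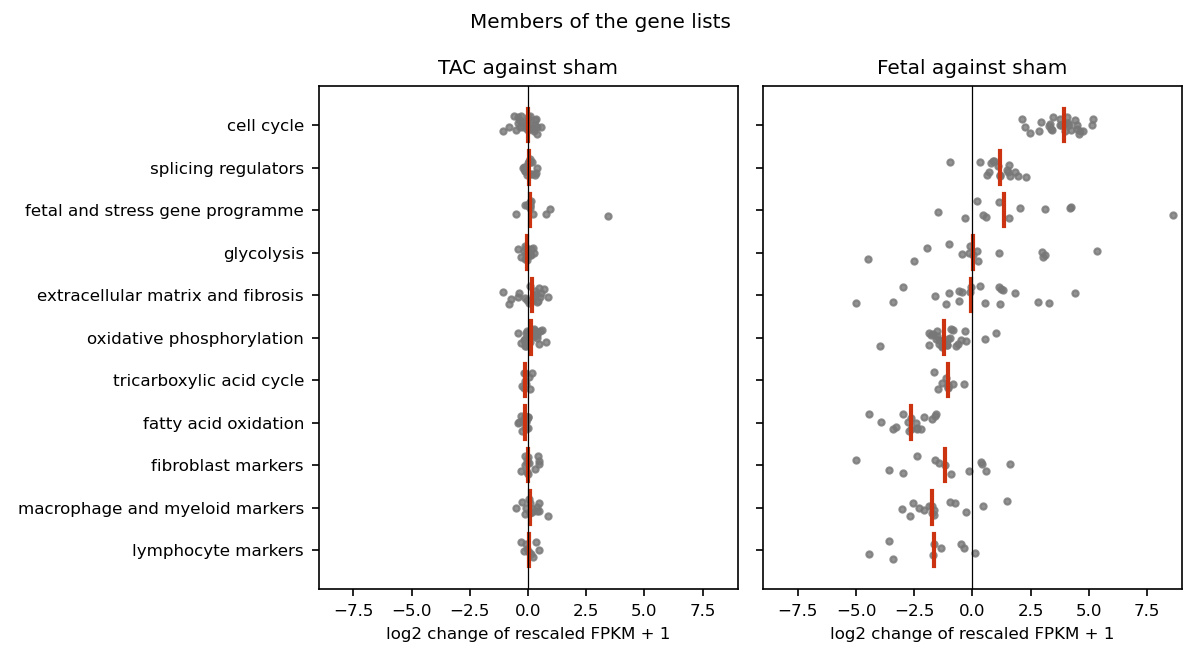
Log2 changes of the members of 11 gene lists between TAC and sham and between fetal and sham, with the median of each list as a red line. Between TAC and sham the medians lie nearer 0, except for glycolysis and matrix genes, and Myl7 (3.42) stands apart.

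At the level of single transcripts, 1821 of 13998 differed between fetal and sham, 658 higher and 1163 lower in fetal. Kcnip2_v2 (a potassium channel partner) had a transcript at 184.8 ± 61.8 in sham that was listed at 0 in fetal. A transcript of Hspb6, a small heat shock protein, fell from 2257 ± 328.2 to 63.7 ± 21.4 (log2 change -5.18). Transcripts of Bex1 (5.60) and Myl9 (4.30) rose with their loci. Of the 1821 transcripts, 1232 are the only reference transcript of their locus, with a median absolute log2 change of 1.92 against 1.75 for the locus, and 235 (12.9%) were listed at 0 in a whole group. Replicates 2 and 3 alone gave 880 transcripts, leaving out fetal replicate 3 gave 1125 and leaving out fetal replicate 1 gave 1199.

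Shares of transcripts within their locus differed at 100 of 6458 transcripts (39 higher, 61 lower). In Rtn4 (reticulon 4; rn4 chromosome 14, from 110725066 to 110772581) ENSRNOT00000051817 held 47.6 ± 13.5% of the locus in fetal and was listed at 0 in the adult libraries, while ENSRNOT00000042965 held 64.2 ± 15.1% in sham, 70.3 ± 4.63% in TAC and 0 in fetal. In Ccng1 (cyclin G1; rn4 chromosome 10, from 25776380 to 25782754) ENSRNOT00000004368 held 31.4 ± 3.94% in sham, 24.9 ± 2.25% in TAC and 0 in fetal. ENSRNOT00000026141 of Tmem223 held 50.8%, 69.4% and 70.4% in sham and 0 in fetal. In Ccng1 the other reference transcript, ENSRNOT00000065633, held 100% in each fetal library. For Rtn4, Tmem223 and the transcript of Kcnip2_v2, a value of 0 in a whole stage may also come from fragments assigned to transcripts assembled in single libraries. This was not tested.

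The share calls depend on single libraries. Without fetal replicate 3 no share was called by limma (675 at an unadjusted p below 0.05), and without sham replicate 3, sham replicate 1, fetal replicate 1, sham replicate 2 or fetal replicate 2 there were 1, 2, 4, 4 and 5, against 68 without TAC replicate 3. With the replicate block 1 share was called, ENSRNOT00000042965 of Rtn4, and with replicates 2 and 3 alone 0 by limma (742 at an unadjusted p below 0.05). ENSRNOT00000042965 of Rtn4 (adjusted p = 0.00603) lost its call without fetal replicate 3 (0.0516). ENSRNOT00000051817 of Rtn4 (0.0211) lost it with the block (0.0946) and without fetal replicates 1 (0.109), 2 (0.0793) or 3 (0.101) or sham replicates 1 (0.0804), 2 (0.0654) or 3 (0.0639). Ccng1 (0.00968) lost it with the block (0.0833) and without fetal replicate 3 (0.0516) or sham replicates 1 (0.0694), 2 (0.0591) or 3 (0.0639), and Tmem223 (0.00968) with the block (0.0833) and without fetal replicate 3 (0.0516) or sham replicate 3 (0.0639). Over the alternatives the adjusted p ran from 0.000595 to 0.168 in Rtn4, from 0.000673 to 0.271 in Ccng1 and from 0.000643 to 0.168 in Tmem223.

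**Figure D3:**
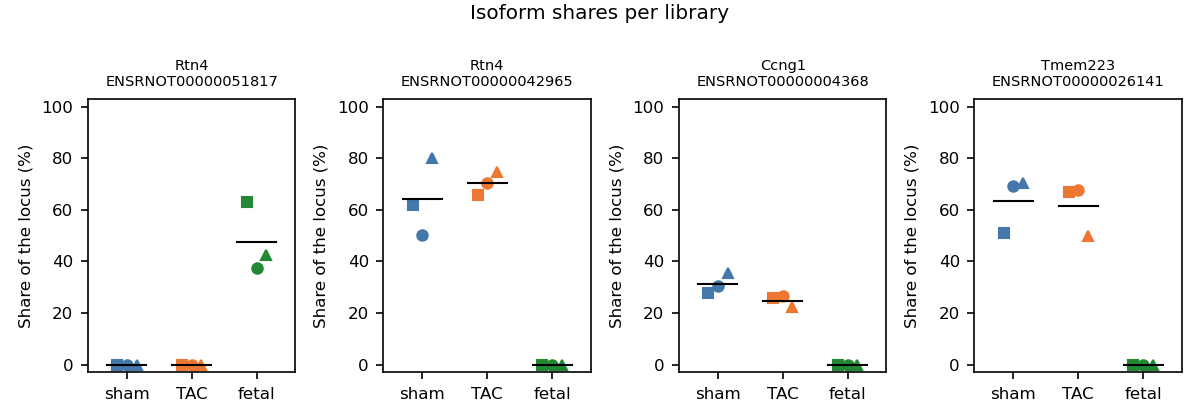
Share of the locus, in percent, of 2 transcripts of Rtn4 and 1 each of Ccng1 and Tmem223 in each library, with replicates 1, 2 and 3 as squares, circles and triangles. The adult groups lie together and the fetal libraries apart.

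Few loci were called after pressure overload: 2 of 14143 passed between TAC and sham, 1 higher and 1 lower. Simulated 2-fold changes were recovered at 19.4%, with 3.3 false calls per draw. So few calls therefore do not show that few genes changed. By limma 609 loci had an unadjusted p below 0.05 in this fit, which leaves out the library batch. That is a smaller share than the 0.05 that unchanged loci would give. The share was larger than 0.05 with the replicate block (758), with the batch covariate (789) and with replicates 2 and 3 alone (828 of 13388). Neither of the 2 called loci has a symbol. The locus of ENSRNOT00000056539 (rn4 chromosome 1, from 91097621 to 91097875) stood at 13.0, 14.2 and 19.6 in TAC and was listed at 0 in sham (adjusted p = 0.000584). The locus of ENSRNOT00000023713 (chromosome 5, from 71384787 to 71385374) stood at 23.2, 26.1 and 10.7 in sham and at 0, 0 and 0.198 in TAC (log2 change -4.21, adjusted p = 0.00489). Its call was lost when only the libraries compared were fitted (adjusted p = 0.091) and on the values as deposited (0.0569), within a range from 0.00327 to 0.091. Without any 1 sham library, or with replicates 2 and 3 alone, it did not pass the filter and was not tested.

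Among genes with a symbol, those with the smallest p-values were not called (n = 3 per group). Igsf8, an immunoglobulin superfamily member, stood at 2.45 ± 0.818 in sham and 6.42 ± 0.440 in TAC (log2 change 1.13), and Zbtb20, a zinc finger repressor, at 22.0 ± 3.98 and 6.76 ± 1.22 (-1.56). Lgals1 (galectin 1) stood at 248.8 ± 28.3 and 367.9 ± 36.2 (0.56), with Dcbld1 (0.81) and Trnp1 (1.21). The adjusted p of these 5 was 1. The stress and fibrosis markers Nppa (0.92), Nppb (0.78), Timp1 (0.86), Dcn (0.43) and Acta1 (0.08) did not pass, with an adjusted p of 1. Nppb stood at 364.5 ± 217.0 in sham and 578.1 ± 190.4 in TAC, and Timp1 at 15.2 ± 7.69 and 26.8 ± 7.21. Myc (0.69), Snrpa1 (0.39), Cdc20 (-1.07), Pkm2 (-0.06) and Rbm20 (0.18) were not called either, again with an adjusted p of 1.

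The list of fatty acid oxidation was lower in TAC: 17 of 17 members lay below 0, with a median of -0.12 (camera adjusted p = 0.0416; adjusted p = 0.833 with an estimated correlation; fry adjusted p = 0.873). Mlycd stood at 217.2 ± 13.8 in sham and 166.1 ± 6.96 in TAC (-0.38), and Acaa2 (-0.41) and Acadm (-0.22) were also below 0, with an adjusted p of 1 for each gene alone. The call was lost without TAC replicate 1 (0.228) or 3 (0.175), or sham replicate 2 (0.395) or 3 (0.108), with no trend in the prior variance (0.0656) and with reference transcripts only (0.0666), within a range from 0.00123 to 0.395. The members below the median of all loci were then 12 without TAC replicate 1, 14 without TAC replicate 3, 11 without sham replicate 2 and 14 without sham replicate 3, against 17. With the replicate block camera called it (adjusted p = 0.0109) and also the atrial list, upward (adjusted p = 0.0109). In the main fit the atrial list had an adjusted p of 0.833 by camera with an estimated correlation and of 0.873 by fry. Replicates 2 and 3 alone gave 6 lists, among them the matrix list, upward (camera adjusted p = 0.0159). In the main fit the matrix list had 0.449 by camera, and 0.833 with an estimated correlation. Leaving out sham replicate 1 also gave 6 lists. There were 4 without TAC replicate 2, 2 without TAC replicate 1 or fetal replicate 1, and 0 by camera without TAC replicate 3 or sham replicate 3 (2 and 1 at an unadjusted p below 0.05).

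Of the other lists none was called in this comparison. The medians and camera's adjusted p were 0.09 and 0.418 for fetal and stress genes, -0.06 and 0.676 for glycolysis, -0.11 and 0.541 for the tricarboxylic acid cycle, 0.11 and 0.449 for oxidative phosphorylation and 0.17 and 0.449 for matrix and fibrosis genes. Cell cycle genes gave -0.02 and 0.604, immediate early genes -0.19 and 0.313, splicing regulators 0.04 and 0.527 and genes with known developmental splicing 0.07 and 0.55. The cell markers gave 0.05 and 0.676 (endothelial), -0.02 and 0.676 (smooth muscle), 0.10 and 0.313 (macrophage), 0.04 and 0.604 (lymphocyte), -0.43 and 0.109 (erythroid), 0.04 and 0.527 (epicardial) and 0.43 and 0.109 (atrial). Fibroblast markers had a median of -0.002, a mean of 0.08 and an upward test (0.418), and neural markers a median of -0.06, a mean of -0.01, an upward camera test and a downward fry test (0.975). Of 261 members 0 passed limma's threshold, over all loci or adjusted over the list alone. In this fit, which leaves out the library batch, an unadjusted p below 0.05 was found for 8, a smaller share than unchanged genes would give. Camera with an estimated correlation, fry and its mixed form each called 0 lists (0, 0 and 0 at an unadjusted p below 0.05, against 3 for camera at the preset correlation).

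The limma test used the same 9 libraries, with a smallest adjusted p of 0.000584. Replicates 2 and 3 alone gave 10 loci (6 higher, 4 lower), the batch covariate 3 and reference transcripts only 41. Leaving out fetal replicate 1 gave 5 and leaving out TAC replicate 2 or sham replicate 2 gave 4. The standard deviation of the log2 changes over all loci was 0.44 and the median standard error 0.256.

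Single transcripts gave more calls than loci: 52 of 13998 passed between TAC and sham, 33 higher and 19 lower. ENSRNOT00000006241 of Arhgap5 stood at 23.4, 21.8 and 20.8 in TAC and was listed at 0 in sham and fetal (adjusted p = 0.0024), although the locus stood at 22.0 ± 1.29 in TAC and 22.7 ± 1.73 in sham. A transcript of Bmp6 stood at 36.8, 16.6 and 16.7 in TAC and was listed at 0 in sham (adjusted p = 0.00786), where the locus stood at 29.2 ± 4.70. A transcript of Dhx38, a splicing helicase, stood at 10.3, 8.23 and 10.2 in TAC and was likewise listed at 0 in sham (adjusted p = 0.00568). With the replicate block Bmp6 (0.0536) and Dhx38 (0.0567) lost the call, and with only the libraries compared Arhgap5 (0.0896), Bmp6 (0.0896) and Dhx38 (0.0981) did. Among the transcripts that fell, ENSRNOT00000063910 had the smallest adjusted p and is described with the overlap. In all, 51 of the 52 (98.1%) were listed at 0 in a whole group. Such a group adds no spread, so the p-values of these calls rest in part on constant zeros. For the 22 that are the only reference transcript of their locus, the median absolute log2 change was 2.88 for the transcript and 0.18 for the locus. For the 30 others the locus moved by 0.11.

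A transcript present in only 3 libraries leaves the test when any of them is left out. Part of the falls with libraries left out therefore follows from the filter. The replicate block and the fit of only the libraries compared tested all 13998 transcripts, so the filter accounts for neither of their falls. With replicates 2 and 3 alone there were 10, the replicate block gave 5 and a fit of only the libraries compared gave 1, ENSRNOT00000063910, lower in TAC. Leaving out 1 library gave from 24 (without TAC replicate 2) to 46 (without fetal replicate 1), with 32 and 30 without TAC replicates 1 and 3, 33 and 33 without fetal replicates 2 and 3, and 27, 31 and 25 without sham replicates 1, 2 and 3. Shares gave 3 calls of 6458 (1 higher, 2 lower; 374 at an unadjusted p below 0.05), among them ENSRNOT00000006241 of Arhgap5 (100% of the locus in each TAC library and 0 in the others, adjusted p = 0.00121). It lost the call with reference transcripts only (0.391) and with replicates 2 and 3 alone (0.236), where limma called 0 shares (284 and 461 at an unadjusted p below 0.05). The adjusted p ranged from 0.000563 to 0.391. Leaving out sham replicate 2 or sham replicate 3 gave 1 share.

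The overlap asks whether overload brings back fetal features. Both loci called between TAC and sham were called between fetal and sham in the same direction: the locus of ENSRNOT00000056539 stood at 10.5, 11.2 and 15.0 in fetal, and that of ENSRNOT00000023713 at 0.0724, 0 and 0. Within replicates 2 and 3 there were 7 such loci. Independent lists would share 0.45 loci, but both comparisons use the same sham libraries, so this is no measure of chance. Simulated data with no difference in any group and unpaired libraries shared 0.01 on average and 1 at most; they leave out the fetal differences and the pairing, so their values are no measure of chance for the overlap found here. Over all loci the covariance of the changes was 0.110, no higher than with the shared sham libraries alone in the simulations (0.127, SD 0.0071). The same held for transcripts (0.457 against 0.466) and shares (1.24 against 1.40). As the simulations leave out the pairing, this does not settle how much comes from the shared controls. Of transcripts 16 were called in both, all in the same direction (independent lists 3.13, simulated mean 0.03). Neither value is a measure of chance here. Of 10 splits of the adult libraries, the real one included, 6 gave as many transcripts, and the highest other gave 45. The replicate block gave 2, replicates 2 and 3 alone 7 and a fit of only the libraries compared 1. Leaving out sham replicate 3 gave 9, in part through the filter.

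The transcript with the largest change in both was ENSRNOT00000063910 of a locus without a symbol (rn4 chromosome 3, from 4508144 to 4520794). It stood at 142.0, 236.1 and 249.9 in sham and was listed at 0 in TAC and fetal (adjusted p = 0.000446). It held 53.8%, 85.0% and 71.5% of its locus in sham, and its share was the 1 share called in both comparisons (adjusted p = 0.00375 and 0.0237). Independent lists would share 0.02, which again leaves out the shared sham libraries. Leaving out any fetal or sham library, the replicate block, and replicates 2 and 3 alone each gave 0 shares by limma. As the 3 sham libraries cannot be divided into 2 sets of 2 or more, part of each overlap may come from the shared controls.

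Fetal ventricle differed from TAC left ventricle much as from sham: 6424 loci passed, 3204 higher and 3220 lower in fetal (equal library totals 3558 and 2244, values as deposited 13374 and 217). Tnni1 rose (log2 change 8.54, adjusted p = 0.000225), as did Prc1, a cytokinesis gene, from 3.31 ± 1.49 to 170.4 ± 19.2 (5.38, adjusted p = 5.8e-06), Bmp7 (5.67) and the glycolytic Aldoc (3.21). Rpl3l fell from 465.8 ± 85.9 to 0.140 ± 0.0241 (-8.66), with Akr1cl1 (-8.21), Myom2 (-8.03), Lpl (-4.44) and the cytochrome oxidase subunit Cox8b (-4.22). Sln (sarcolipin) was lower in fetal (-3.55, adjusted p = 0.0209), with the call lost without TAC replicate 1 (0.0663) or fetal replicates 2 (0.0698) or 3 (0.0683). Nppa (1.10, adjusted p = 0.253, but 0.0397 without TAC replicate 1), Acta1 (1.48, adjusted p = 0.0671) and Rbm20 (0.45, adjusted p = 0.125) were not called.

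The lists called against TAC were cell cycle (28 of 28 higher, median 4.11, camera adjusted p = 1.82e-17; adjusted p = 0.0741 with an estimated correlation), fatty acid oxidation (17 of 17 lower, -2.38, 2.78e-12; adjusted p = 0.0741 with an estimated correlation) and splicing regulators (13 of 17 higher and 1 lower, 1.16, 7.35e-05; adjusted p = 0.0693 with an estimated correlation). Oxidative phosphorylation (22 of 28 lower, -1.28, 2.33e-06; adjusted p = 0.24 with an estimated correlation) and the tricarboxylic acid cycle (8 of 9 lower, -1.09, 0.000507; adjusted p = 0.163 with an estimated correlation) fell. So did macrophage (12 of 15 lower and 1 higher, -2.10, 7.35e-05; adjusted p = 0.0741 with an estimated correlation), lymphocyte (6 of 9 lower, -1.60, 0.00293; adjusted p = 0.0741 with an estimated correlation) and fibroblast markers (8 of 13 lower and 1 higher, -1.13, 0.0199; adjusted p = 0.445 with an estimated correlation). Erythroid markers rose (6 of 9, 1.52, 0.013; adjusted p = 0.24 with an estimated correlation). Adjusted over the list alone, the counts were 14 higher for splicing regulators, 23 lower for oxidative phosphorylation, 9 lower for the cycle, 7 lower for lymphocyte markers, 8 higher for erythroid markers and 4 higher for smooth muscle markers, and otherwise the same.

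Not called against TAC were fetal and stress genes (camera adjusted p = 0.0813), epicardial (0.0781), smooth muscle (0.109), endothelial (0.162), developmental splicing (0.188), neural (0.223), glycolysis (0.461), immediate early (0.461), atrial (0.461) and matrix genes (0.553). Transcripts gave 1901 calls (679 higher, 1222 lower) and shares 127 (46 higher, 81 lower). Neither count was run with the processing alternatives, nor was that of the lists. The matching count of shares against sham fell from 100 to 0 by limma without fetal replicate 3. The limits of the design are those of the comparison with sham, since age, region and isolation differ alike. Replicates 2 and 3 alone gave 4951 loci and reference transcripts only 2137, where Myom2 (2.03), Col12a1 (-0.36), Vwf (0.0737), Ctss (0.61), Cd4 (1.33) and Stard10 (1.52) turned.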

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

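Tests chosen only after the result was seen were the batch covariate, replicates 2 and 3 alone, the splits of transcripts, shares and lists between fetal and TAC and of transcripts called in both comparisons, both tests of fetal signal in replicate 1, and the regions outside reference loci.

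Signal lies outside the loci that the comparisons use. Of 17352 assembled regions that overlap no reference locus, 43 stood at 5 or more in all TAC libraries and were listed at 0 in all sham libraries, against 30 the other way round. For fetal against sham there were 106, against 145 the other way round, and between fetal and TAC 145 against 221. The TAC regions with the highest lowest value lie on chromosome 7 (from 142153583 to 142154696, 3 nt from ENSRNOT00000055282, lowest value 58.0), on chromosome 5 (from 59190184 to 59191176, 1521 nt from Il11ra1, 26.4) and on chromosome 13 (from 96489240 to 96490078, 97 nt from Acbd3, 23.4). Those of fetal lie on chromosome 1 (from 110708296 to 110708520, 20999 nt from Ube3a, 344.1), on chromosome 16 (from 31193359 to 31193652, 160.4) and on chromosome 3 (from 163721625 to 163722650, 1051 nt from Bmp7, 48.1). Regions so close to a locus can be unannotated parts of it, and a region can be listed at 0 because it was joined to a locus in that library; neither was tested.

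Few loci passed between TAC and sham (2). A swapped pair of labels would bring out many more loci once undone if the response were strong. The most after exchanging 1 TAC library with 1 sham library was 7. A weak response could stay uncalled with the labels restored, so a swap is not excluded. Spread between library batches would hide calls that a batch covariate frees, and that covariate gave 3, but replicates 2 and 3 alone gave 10, so such spread stays open. Lower depth of the TAC libraries would spare deep loci. Yet limma called 0% of the 3196 loci with at least 100 implied fragments in each adult library. There 116 had an unadjusted p below 0.05, a smaller share than unchanged loci would give, in a fit that leaves out the library batch. This speaks for these loci only, and depth stays open for the others. Also open is a weak response in the groups as sampled, since simulated 2-fold changes were recovered at 19.4% and the time after surgery is not given.

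Transcripts gave 52 calls where loci gave 2. Each library was assembled separately, so fragments may be assigned to a reference transcript in one library and to an assembled variant in another. In that case the locus would hardly move, and in the 22 called transcripts that are alone in their locus the locus moved by a median of 0.18, against 2.88 for the transcript. Of the 21 among these that were listed at 0 in a whole group, the locus moved by 1 or more in 2, against 60 of 88 such transcripts between fetal and sham, but as few loci moved at all between TAC and sham a small value was to be had in any case. A true switch to another transcript, annotated or assembled anew, is the biological explanation that the groups offer; it would leave the locus unmoved as well (0.11 in the other 30) and stays open and untested for all 52, beside assignment.

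In replicate 1 of both adult groups, many transcripts that are high in fetal libraries stood above replicates 2 and 3. Over the 188 loci that are 16 to 64 times higher in fetal libraries, TAC replicate 1 lay 0.70 above replicates 2 and 3 (quartiles 0.00 and 1.38) and sham replicate 1 lay 0.55 above them (quartiles -0.14 and 1.11), the lower value being the test of fetal RNA or reads in these libraries. In TAC replicate 1 the step grew with the fetal excess, in sham replicate 1 not at every stage (0.42 and 0.16 at 8 to 16 times, 0.20 and 0.19 at 4 to 8, 0.10 and 0.07 at 2 to 4), and it was 0.00 in both over the 72 loci above 64 times. From 4 to 64 times the median excess amounted to between 1.02% and 3.23% of the value in fetal replicate 1. Above 64 times it was 0.33% in TAC replicate 1 and 0% in sham replicate 1. Of those loci 48.6% and 43.1% were raised, too few for a median to show an excess. In replicates 2 and 3 between 14.3% and 23.2% of such loci were raised. The range above 64 times therefore does not decide whether the share was constant. These loci were picked on replicates 2 and 3 of both stages, which also serve as the baseline, so the picking can itself raise replicate 1. Picked alike on the other numbers, replicates 2 and 3 of the adult groups lay between -0.43 and -0.23 at 16 to 64 times. Over 153 loci picked on replicate 1, TAC replicate 3 against TAC replicate 2 gave 0, and sham replicate 3 against sham replicate 2 gave -0.1. Compressed differences in the batch would raise adult transcripts in fetal replicate 1 alike, and over 171 loci 16 to 64 times higher in adults the median was 0. Fetal RNA or reads in replicate 1 therefore stay open, a single source cannot be told apart from other differences of that batch, and no biological explanation was tested, since no label sets replicate 1 apart.

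The 6 libraries of a comparison have 10 splits, the real one included, too few for a share under 0.05. For TAC against sham the real value and the highest other were 2 and 7 for loci (7 splits as large), 52 and 75 for transcripts (2), 3 and 4 for shares (3) and 1 and 9 for lists (9). For features called in both comparisons they were 2 and 6 for loci (7), 16 and 45 for transcripts (6) and 1 and 2 for shares (3). For fetal against sham they were 6415 and 1 for loci, 1821 and 13 for transcripts, 100 and 1 for shares and 11 and 10 for lists, with 1 split as large, the real one. For fetal against TAC they were 6424 and 2, 1901 and 24, and 127 and 2, again with 1 split, and 9 and 9 for lists (2).

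The splits that keep replicate 1 of TAC and of sham on the same side follow the library batch. They gave 7, 2, 7 and 7 loci, 49, 23, 44 and 75 transcripts and 5, 9, 3 and 3 lists, which points to a structure of the samples by batch. Their shares, 1, 0, 0 and 3, show no such structure. Replicates 2 and 3 alone gave 10 loci, 10 transcripts and 6 lists. The other splits that part all 3 pairs, as the real one does, gave 1, 2 and 1 loci, 33, 25 and 25 transcripts, 4, 0 and 0 shares and 1, 2 and 3 lists. The remaining splits gave 1 and 3 loci, 16 and 32 transcripts, 0 and 0 shares and 0 and 1 lists.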

How the results depend on the processing

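The status alternative was not run, because the files hold no status column, and neither the filter settings nor quantile normalization apply to shares. The values as deposited, equal totals, reference transcripts only, no minimum length, the batch covariate, replicates 2 and 3 only, libraries weighted by their spread and every setting of transcripts called in both comparisons were chosen after seeing the data. Where no cause is given, the cause was not tested.

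Loci. Between TAC and sham (2 called) the values as deposited gave 57, reference transcripts only 41, replicates 2 and 3 only 10, and leaving out 1 library from 2 to 5. Against sham, fetal (6415) gave on the values as deposited 11538, reference transcripts only 2056 and leaving out 1 library from 4949 to 6609. Against TAC (6424) these gave 13591 and 2137, and leaving out 1 library from 4944 to 6333. Called in both (2): only the libraries compared 1, values as deposited 14, reference transcripts only 13, replicates 2 and 3 only 7, leaving out 1 library from 2 to 3.

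Lists. Between TAC and sham (1): no filter 2, replicate block 2, no trend 0 (3 at an unadjusted p below 0.05 by camera), values as deposited 3, equal totals 2, reference transcripts only 0 (4), batch covariate 2, replicates 2 and 3 only 6, weighted libraries 2, estimated correlation 0 (0), fry 0 (0), leaving out 1 library from 0 to 6 (0 without TAC replicate 3 or sham replicate 3, 2 without TAC replicate 1 or fetal replicate 1, 4 without TAC replicate 2, 6 without sham replicate 1). Fetal against sham (11): filter of 5 gave 7, values as deposited 6, camera with an estimated correlation 0 (6), leaving out 1 library from 9 to 11.

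Transcripts. Between TAC and sham (52): pseudocount of 0.1 gave 89, filter of 5 14, only the libraries compared 1, replicate block 5, values as deposited 154, replicates 2 and 3 only 10, leaving out 1 library from 24 to 46. Leaving out a TAC or sham library takes transcripts present in only 3 libraries through the filter, so these falls follow in part from it. Fetal against sham (1821): values as deposited 5007, replicates 2 and 3 only 880, leaving out 1 library from 1125 to 1984. Called in both (16): pseudocount of 0.1 36, filter of 5 7, only the libraries compared 1, replicate block 2, values as deposited 65, replicates 2 and 3 only 7, leaving out 1 library from 9 (without sham replicate 3) to 19.

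Shares. Between TAC and sham (3): values as deposited 67, reference transcripts only 0, replicates 2 and 3 only 0, leaving out 1 library from 1 to 4. Fetal against sham (100): pseudocount of 0.1 gave 59, only the libraries compared 175, replicate block 1, arcsine of the share 3, a gene mean of at least 10 47, values as deposited 153, reference transcripts only 39, batch covariate 60, replicates 2 and 3 only 0, weighted libraries 152, leaving out 1 library from 0 to 129. Called in both (1): replicate block 0, values as deposited 22, reference transcripts only 0, replicates 2 and 3 only 0, leaving out 1 library from 0 to 1. Where limma called 0 shares with reference transcripts or with replicates 2 and 3, 284 and 461 had an unadjusted p below 0.05 between TAC and sham, and 742 between fetal and sham with replicates 2 and 3. Beyond the counts of lists, transcripts and shares given above, the replicate block changed no count that was run with it by more than 1.5-fold. Counts of transcripts, shares and lists between fetal and TAC were not run with the block or the other processing alternatives.

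Turns of named genes called in neither the main setting nor the alternative were not counted. Among the other named genes, turns came only with reference transcripts only, which drops transcripts assembled anew. Between fetal and sham the genes that turned were Myom2 (2.03), Dcn (1.59), Col12a1 (-0.30), Mcm3 (-1.20), Tgfb2 (-0.48), Vwf (1.75) and Esam (0.0424). Between fetal and TAC they were Myom2 (2.03), Col12a1 (-0.36), Vwf (0.0737), Ctss (0.61), Cd4 (1.33) and Stard10 (1.52). Over all settings, called named loci between fetal and sham kept call and direction in 1967 of 2079 values and lost the call in 105. Between fetal and TAC this was 2015 of 2071 and 50, between TAC and sham 42 of 44 and 2. Named transcripts kept both in 377 of 546 values between TAC and sham and 413 of 462 between fetal and sham, and named shares in 45 of 52 and 190 of 284.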

Other observations

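Genes of the atrium varied from library to library within the adult groups and, for Myl7 and Sln, stood higher in every TAC library than in any sham library (no overlap in either direction comes by chance in 10% of genes); they were singled out after their values were seen. Myl7 (atrial myosin light chain) stood at 1070.0, 147.3 and 105.4 in TAC replicates 1 to 3 and at 75.2, 80.6 and 1.22 in sham. Sln (sarcolipin) stood at 98.6, 24.8 and 23.2 in TAC and 11.3, 3.98 and 1.26 in sham, and Nppa at 1782, 254.7 and 528.1 in TAC and 543.4, 423.8 and 152.7 in sham. In TAC replicate 1 all 3 were at their highest among the adult libraries. Between TAC and sham neither Myl7 (log2 change 3.42, adjusted p = 1) nor Sln (2.94, adjusted p = 1) passed, nor with the replicate block (0.905 and 0.406). With the block camera called the atrial list upward (adjusted p = 0.0109). Without the block the list's adjusted p by camera was 0.109 at the preset correlation and 0.833 with an estimated one.

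Some transcripts were present in replicate 1 of both adult groups and listed at 0 in replicates 2 and 3; those named were chosen after their values were seen. Cap2 stood at 65.0 in TAC replicate 1 and 46.0 in sham replicate 1, and at 75.1, 129 and 0 in fetal. Ensa stood at 23.6 and 22.4, and at 17.4, 26.3 and 20.3 in fetal.

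Values of 0 are common and come beside high values in the same group. Of 14143 tested loci 1476, and of 13998 tested transcripts 7409, were at 0 in at least 1 library. In 346 loci and 3080 transcripts a 0 stood beside a value of 10 or more in the same group.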
